A study of Mus musculus with 11 samples.

How the data were processed

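Hydroxymethylated DNA immunoprecipitation sequencing (hMeDIP-seq) captures DNA fragments that carry 5-hydroxymethylcytosine (5hmC) with an antibody and sequences them. The assay was run on DNA from neuronal nuclei that were sorted out of mouse hippocampus. Per the labels' protocols, C57BL/6 mice received a lentivirus at 3 months of age and were killed 60 days later. The virus carried either GFP or Tet2, in both cases driven by the synapsin promoter, which is active in neurons. DNA was sheared to between 300 and 500 bp before capture. The labels give 11 samples, 5 in the GFP group and 6 in the Tet2 overexpression group (Tet2OE).

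The deposited files hold 2 genome-wide signal (coverage) tracks, 1 per group, and name no library. The tracks are called pooled here, but pooling was inferred from there being 1 track per group. Which libraries entered each track, and how many, is not given in the sources used here. Alignment with Bowtie2, use of MACS2 and the mouse build mm10 are named per the submitters' processing notes, without versions. Every value below therefore rests on the authors' pooled track for a group, and no spread between mice, no test between groups and no p-value could be computed.

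The form of the tracks was read from their values. All values of the deposited Tet2OE signal track were whole multiples of 0.0476 within a tolerance of 1e-05, so the track is a pileup of whole fragments times a constant. Its intervals numbered 78024377, with a mean of 5.26 fragments per bp and 22.3% of positions at 0. Upward steps of the pileup set a lower limit of 40577532 fragments. The deposited GFP signal track had another form. Its values never fell below a floor of 0.365, which covered 72.0% of positions. Another 20.7% of positions held whole multiples of 0.202, and 6.23% and 1.01% held averages over windows of 1000 and 10000 bp. No position fell outside these 4 kinds of value, at the same tolerance of 1e-05, widened in proportion to the value. The floor equalled the total Tet2OE signal divided by 1870011954 bp. This is the form of the local background that MACS2 computes from a control when the control is set against a treatment. The GFP track thus stands on the scale of the Tet2OE track and keeps, at each position, the largest of several smoothed estimates. If 1 step stands for 1 fragment end under the depth scaling of MACS2, the track came from 4956463 fragments, a depth inferred from the values and not stated in the labels.

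Because a pileup and a local background cannot be divided by each other directly, the main computation departed from the plan made before the data were examined, which assumed a pair of tracks of the same form. Tet2OE fragments were rebuilt from the pileup and thinned at random to 13 shares between 0.01 and 1.0 of their number. The thinned fragments were put through the same floor, end pileup and windows as the GFP track. For each feature, the share at which thinned Tet2OE fragments gave the GFP signal was read off, which gave an estimate of GFP fragments. Densities were divided by the mean over autosomes of the same track. The ratio was log2 of Tet2OE over GFP with a pseudocount of 0.1 on this relative scale, and a feature was called higher or lower in Tet2OE at a log2 ratio of at least 0.5 in size. Relative values carry no information on the total amount of 5hmC per cell.

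Counting error was measured with 20 further draws in which Tet2OE fragments were thinned to 12.2% of their number, the GFP depth, put in the GFP form and compared with the full Tet2OE track. The spread of a feature over these draws is given after ± as its counting SD, which covers counting error only and not the error between mice or libraries. Where GFP density was below that of Tet2OE, this SD may understate the error of the GFP estimate. The same draws gave the number of calls that depth and form produce without any difference between groups. The procedure was tested on simulated data of genes of at least 20 kb. Of 100 genes with a simulated GFP fold of 0.5, 95.0% were called, of 99 genes with a fold of 1.5, 59.6% were called, and of 9546 unchanged genes, 3.71% were called.

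Gene positions came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. It gave start and end of 49943 genes on the chromosomes used, of which 48872 could be measured. The table gave no strand and no exons, and no genome sequence was used, so promoters, exons, introns, GC content, CpG islands and repeats were not analysed here. Overlapping and nested genes share sequence and so share signal. The 1 kb bins in the top 0.1% of either track, 4631 bins in all, were left out of the reported values. This removal had been listed before the data were examined as an alternative and was moved into the reported values afterwards, since 10 positions held 3.22% of the GFP signal. Values with these bins kept are given as an alternative.

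Genes to be named were chosen by a rule of size fixed before the data were examined. Eligible genes were protein-coding, autosomal or on X, at least 5000 bp long and held at least 100 estimated fragments in the shallower track. By chance their number, 4631, equals that of the bins left out. Named were the 10 eligible genes with the largest and the 10 with the smallest ratio whose parts on either side of the gene's midpoint both moved in the direction of the whole, the 5 with the highest signal in each track, the extremes of each of 28 gene lists, and all members of the list of 5hmC pathway genes; a few genes that this rule names are not reported here. The lists were also fixed beforehand. The median log2 ratio of a list was ranked among 10000 random lists of equal size matched on gene length and mean signal, and its median signal among random lists matched on length, as a description of these tracks. Both kinds of random list were drawn from all genes measured, protein-coding or not.

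Alternatives comprised median centring, quantile normalization, removal of a lowess trend (span 0.3) on mean signal, subtraction of a background level, other pseudocounts, a filter on low signal, other thresholds, gene classes and bin sizes. Alternatives added after the data were examined were keeping the extreme bins, trimming both gene ends, using autosomes only and taking the deposited values as they stand. The mean signal of feature classes carries a standard error from 100 bootstrap draws of 1 Mb blocks, which covers the choice of loci only. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9.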

Results

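The data describe where 5hmC lay in the genome of hippocampal neurons of mice whose neurons had received a lentivirus with GFP or with Tet2. TET2 is a dioxygenase that oxidises 5-methylcytosine to 5hmC, and the comparison addressed which sequences differed in 5hmC when neurons carried additional Tet2. The groups held 5 GFP and 6 Tet2OE samples, and each group was represented by 1 signal track of the authors, inferred to be a pool. How many of the samples entered each track is not known. The Tet2OE track held at least 40577532 fragments and the GFP track an estimated 4956463. With 1 track per group, differences are described by size and by counting error (± counting SD), and none was tested against the spread between mice.

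Among eligible genes raised on both sides of their midpoint, the largest Tet2OE over GFP ratio was that of Hk2, a hexokinase that starts glycolysis. It lies on chromosome 6 from 82725025 to 82774454 and had 2.92 times the autosomal mean in Tet2OE and 1.37 times in GFP, a log2 ratio of 1.04 ± 0.08. Next came D630003M21Rik at 1.03 ± 0.10, Wscd2 at 0.99 ± 0.05, the inward rectifier potassium channel gene Kcnj12 at 0.97 ± 0.09 and Egln1, a prolyl hydroxylase of hypoxia-inducible factor, at 0.97 ± 0.08. Tpst2, a tyrosylprotein sulfotransferase, had 0.96 ± 0.07, the bicarbonate transporter gene Slc4a8 0.95 ± 0.08, and the collagen gene Col17a1 0.94 ± 0.07. Mta1, a subunit of the NuRD chromatin remodelling complex, had 0.94 ± 0.08 and Gnaz, a G protein alpha subunit, 0.93 ± 0.09. A stretch that held bins left out as extreme overlapped Gnaz. With the trend of ratio on mean signal removed, these 10 genes had between 0.32 and 0.496, so 0 of them stayed at the threshold of 0.5.

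Gene bodies with the smallest ratio were led by zinc finger genes of chromosome 4. Zfp600, on chromosome 4 from 146156827 to 146198756, had 0.58 times the autosomal mean in Tet2OE and 2.10 times in GFP, a log2 ratio of -1.70 ± 0.21, and Zfp980 had -1.51 ± 0.24. Nearby Gm42346 had -1.49 ± 0.26. Long genes with little 5hmC followed: the fibrillar collagen gene Col11a1 at -1.45 ± 0.13, Skint5 at -1.35 ± 0.09, Mme, which encodes the amyloid-degrading peptidase neprilysin, at -1.35 ± 0.20, and Phip at -1.35 ± 0.16. The predicted genes Gm8126, Gm21119 and Gm5373 had -1.38 ± 0.14, -1.35 ± 0.12 and -1.31 ± 0.13. Stretches that held bins left out as extreme overlapped Zfp600, Gm8126, Gm21119 and Gm5373, so the values of these genes rest on their other bins. With the trend removed, 8 of the 10 stayed lower, and Phip and Skint5 did not, at -0.48 and -0.40.

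The genes with the highest Tet2OE signal had a high ratio, which this choice favours, since Tet2OE signal is the numerator of the ratio. Of the 5 genes highest in GFP, only Scube3 was called higher. In Tet2OE the highest gene bodies were Scube3 at 4.17 times the autosomal mean, the F-box gene Fbxo31 at 4.15, Pmepa1 at 4.00, the ciliary gene Nphp4 at 3.99 and the ubiquitin ligase gene Ube3b at 3.99. Their log2 ratios were 0.60 ± 0.06, 0.71 ± 0.08, 0.79 ± 0.07, 0.73 ± 0.05 and 0.76 ± 0.07, but all 5 came within the threshold with the trend removed, from -0.03 for Scube3 to 0.16 for Pmepa1. In GFP the highest were C130026I21Rik at 3.47, Celsr3, a cadherin of planar cell polarity, at 2.94, Sp110 at 2.84, Scube3 at 2.72 and Dok7, which acts at the neuromuscular synapse, at 2.72. Stretches that held bins left out as extreme overlapped Nphp4 and Ube3b as well as C130026I21Rik and Sp110. C130026I21Rik and Sp110, both on chromosome 1 near 85 Mb, had ratios of -0.60 ± 0.09 and -0.20 ± 0.10, while Celsr3 had 0.32 ± 0.09 and Dok7 0.39 ± 0.07. With the trend removed this contrast in sign ended, with C130026I21Rik at -1.22, Sp110 at -0.82, Celsr3 at -0.31 and Dok7 at -0.23.

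Among the 4631 eligible genes, 1335 were higher in Tet2OE (28.8%) and 600 were lower (13.0%), where thinned Tet2OE draws gave 2.35 higher and 0.3 lower on average. The ratio followed the Tet2OE signal of the gene: Spearman's rho across genes, which are not independent replicates, was 0.93 between Tet2OE signal and ratio, against -0.05 in the draws. Tet2OE signal is the numerator of the ratio, which favours a positive rho and a rise over quintiles of that signal. The draws were thinned from the same Tet2OE fragments, so their small rho was built in. From the lowest to the highest quintile of Tet2OE signal, median log2 ratios were -0.59, -0.02, 0.29, 0.50 and 0.63. The median over eligible genes lay at 0.28. Centred on it, 89 genes were higher and 1018 lower, and quantile normalization gave 32 and 80. With the trend on mean signal removed, 58 were higher and 59 lower, so the balance of higher and lower calls depended on the scaling. Over all 48872 genes measured, 18275 were higher and 10358 lower, where draws gave 10883 and 3463. Centring gave 11380 and 14273 there, quantile normalization 9943 and 12716, and removal of the trend 10688 and 9450.

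**Figure D1:**
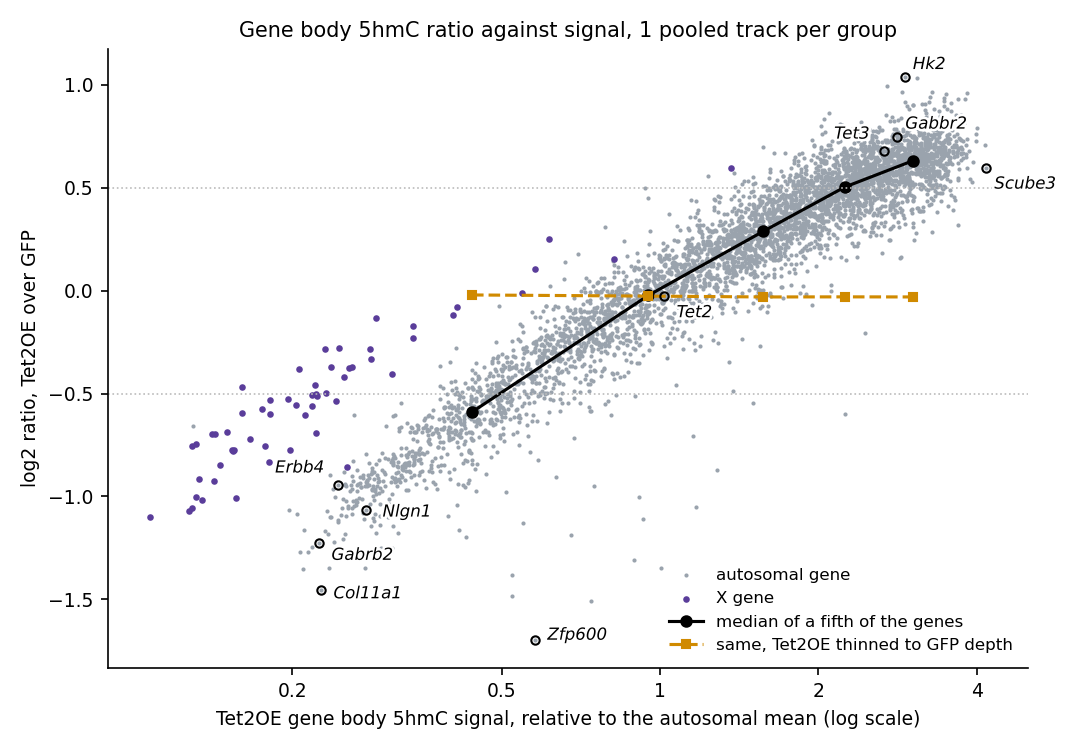
Log2 ratio of Tet2OE over GFP (vertical) against Tet2OE gene body signal relative to the autosomal mean (horizontal, log scale) for 4631 eligible genes, with autosomal genes in grey and X genes in purple. Black circles are medians of signal quintiles, from -0.59 to 0.63, and orange squares are the medians of Tet2OE thinned to the GFP depth, which lie between -0.03 and -0.02.

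Genes of the synapse had calls in both directions. Of 27 eligible genes of glutamatergic transmission and plasticity, 6 were higher, 11 lower and 10 within the threshold. Cacng2, which encodes the AMPA receptor subunit stargazin, had a log2 ratio of 0.74 ± 0.04 with 2.84 times the autosomal mean in Tet2OE, and Nlgn1, the postsynaptic adhesion molecule neuroligin 1, had -1.07 ± 0.09 with 0.276 times. Of 11 eligible genes of GABA receptors and their synapses, 3 were higher, 6 lower and 2 within, from Gabbr2, a GABA-B receptor subunit, at 0.75 ± 0.04 to Gabrb2, a GABA-A receptor subunit, at -1.23 ± 0.11. Of 18 eligible genes of presynaptic vesicles, 7 were higher, 2 lower and 9 within, with the calcium sensor gene Syt7 at 0.84 ± 0.07 and Ppfia2, a liprin of the active zone, at -0.86 ± 0.08. Of 24 eligible voltage-gated ion channel genes, 8 were higher, 9 lower and 7 within, with the potassium channel gene Kcnh7 lowest at -1.06 ± 0.10. With the trend on signal removed, each of the 7 genes named here was within the threshold, from -0.28 for Gabrb2 to 0.23 for Syt7. Over all eligible genes 28.8% were higher and 13.0% lower.

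Axon guidance and adhesion genes were more often lower than higher: 5 of 31 eligible genes were higher, 16 lower and 10 within. Plxna1, a semaphorin receptor, had 0.78 ± 0.09 and the semaphorin gene Sema3a -1.09 ± 0.06, which came to 0.17 and -0.16 with the trend on signal removed. The list had a median of 0.454 times the autosomal mean in Tet2OE and 0.678 in GFP, and GABA receptor genes had 0.360 and 0.658. Each of these medians lay at or below the 0.01 percentile of random lists of matched gene length. The median log2 ratios of the 2 lists were -0.51 and -0.62, at the 23.83 and 18.4 percentiles of random lists matched on length and signal. These lie within the central 95%. With the trend on signal removed, the medians came to -0.03 and 0.01. Pooled over their bodies, the ratios were 0.03 ± 0.01 and 0.17 ± 0.02, opposite in sign to the medians. All 11 eligible clustered protocadherin genes were within the threshold, between Pcdhga12 at 0.28 ± 0.09 and Pcdha12 at -0.29 ± 0.10, with shared sequence among overlapping members.

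Markers of cell types were compared next, since sorted nuclei can hold other cells. Of 8 eligible markers of excitatory neurons, 2 were higher, 1 lower and 5 within. They ran from the calcium/calmodulin kinase gene Camk2b at 0.66 ± 0.05 to the transcription factor gene Mef2c at -0.93 ± 0.13. A stretch that held bins left out as extreme overlapped Camk2b. Of 6 markers of inhibitory neurons, 1 was higher, 2 lower and 3 within. The neuregulin receptor gene Erbb4 was lowest at -0.94 ± 0.04. Of 10 markers of hippocampal subfields, 3 were higher, 2 lower and 5 within, between Mpped1 at 0.69 ± 0.04 and the cation channel gene Trpc6 at -0.88 ± 0.17. Among glial and vascular markers, 1 of 5 astrocyte, 3 of 4 oligodendrocyte, 0 of 2 microglial and 4 of 8 endothelial or pericyte genes were higher, and the microglial gene Ptprc, which encodes CD45, was lower at -0.95 ± 0.13. Mbp, a major protein of myelin, had 0.66 ± 0.05, the astrocyte gene Aldh1l1 0.59 ± 0.08 and the endothelial adhesion gene Pecam1 0.65 ± 0.07. With the trend on signal removed, each marker named in this paragraph was within the threshold, from -0.27 for Trpc6 to 0.11 for Pecam1, and Ptprc and Erbb4 changed sign, to 0.01 and 0.05.

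Genes of the 5hmC pathway did not stand apart. Of 6 eligible members, 3 were higher and 3 within: the dioxygenase gene Tet3 had 0.68 ± 0.06, the methyltransferase genes Dnmt3a and Dnmt1 0.64 ± 0.05 and 0.53 ± 0.07, Tet1 0.31 ± 0.08, the methyl-CpG binding gene Mbd2 0.25 ± 0.12 and Tet2 itself -0.03 ± 0.13. The 3 calls ended with the trend on signal removed, at 0.12 for Tet3, 0.04 for Dnmt3a and -0.07 for Dnmt1. Of members below the depth limit, Hells, a remodelling helicase gene, had the lowest ratio at -0.91 ± 0.22, followed by Uhrf2 at -0.76 ± 0.20 and Zbtb33 on X at -0.69 ± 0.60. Mbd1 had 0.67 ± 0.15, Idh2 0.58 ± 0.13, Tdg, a glycosylase of active demethylation, 0.51 ± 0.16, Mbd3 0.45 ± 0.26, Wdr76 0.42 ± 0.17, Neil1 0.38 ± 0.21, Dnmt3b 0.37 ± 0.14 and Uhrf1 0.32 ± 0.11. Further members were Apex1 at 0.28 ± 0.40, Neil2 at 0.25 ± 0.20, Idh1 at 0.25 ± 0.22, Smug1 at 0.23 ± 0.18, Gadd45b at 0.17 ± 0.20, Mbd4 at -0.10 ± 0.26, Gadd45a at -0.28 ± 1.11, Ogt at -0.44 ± 0.16 and Gadd45g at -0.46 ± 0.20. The list's median of 0.25 lay at the 23.9 percentile of matched random lists.

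Genes near risk loci of Alzheimer's disease were rich in 5hmC. Their 29 members had a median of 2.28 times the autosomal mean in Tet2OE and 1.47 in GFP, at the 99.95 and 99.6 percentiles of random lists of matched length. Those random lists also held noncoding genes and pseudogenes, and a high rank was not particular to this list. Endothelial or pericyte, microglial, sperm and immediate-early genes lay at 98.31, 98.28, 98.35 and 98.14 in Tet2OE. In GFP the same lists lay at 95.04, 78.88, 6.32 and 99.93. Of 17 eligible members 7 were higher, 2 lower and 8 within, with the cation exchanger gene Slc24a4 at 0.67 ± 0.05 and Mef2c lowest. Of 11 eligible genes of memory and aging, 4 were higher and 7 within, from the receptor gene Igf1r at 0.66 ± 0.04 to the coactivator gene Ppargc1a at -0.35 ± 0.05. Immediate-early genes, which neurons transcribe upon activity, had medians of 2.28 in Tet2OE and 1.89 in GFP over 22 genes, and none reached the depth limit. Of 6 eligible imprinted genes, 1 was higher, 1 lower and 4 within, with Igf2r at 0.57 ± 0.05 and Snrpn at -0.96 ± 0.09. Of 5 eligible developmental transcription factor genes regulated by Polycomb, 1 was higher and 4 within, with Pax7 at 0.56 ± 0.05 and Tbx15 at -0.31 ± 0.12. With the trend on signal removed, no gene named in this paragraph kept its call: Mef2c had -0.15, Snrpn -0.11, Pax7 -0.03, Igf2r 0.01, Slc24a4 0.13 and Igf1r 0.14.

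Genes of the olfactory and vomeronasal receptors, which act in sensory neurons of the nose, were poor in 5hmC in both tracks. Over 1402 olfactory receptor genes the median was 0.282 in Tet2OE and 0.627 in GFP, and over 616 vomeronasal receptor genes 0.225 and 0.590. Pooled over their bodies, log2 ratios were -0.33 ± 0.02 and -0.91 ± 0.03. Vmn2r1, the eligible vomeronasal gene, had -0.66 ± 0.16. Of 5 eligible sperm genes 2 were lower and 3 within, with Tdrd9 at 0.39 ± 0.07 and Zpbp at -0.68 ± 0.12. Further lists with 2 or fewer eligible genes included those of neural stem cells (Prom1 at 0.28 ± 0.08 and Lpar1 at 0.02 ± 0.09), innate immunity (Nfkb1 at 0.53 ± 0.08), housekeeping (Rab7 at 0.03 ± 0.10), nuclear genes of mitochondrial respiration (Ndufs4 at -0.13 ± 0.13), and liver, muscle and keratinocyte genes (Ttn at -0.04 ± 0.06). With the trend on signal removed, Vmn2r1, Zpbp and Nfkb1 came within the threshold, at 0.00, -0.05 and 0.21. Of 32 ribosomal protein genes none was eligible, and their median ratio was 0.34.

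Against 10000 random lists matched on length and signal, 7 of the 28 lists had a median ratio outside the central 95%. With independent genes and lists, 1.4 would fall there by chance. Some lists share members, such as Mef2c, and overlapping genes share signal, so 1.4 is only a rough guide. All 7 lay on the low side in the reported values. They were olfactory receptors and vomeronasal receptors, both at percentile 0, inhibitory neuron markers at 1.21, imprinted genes at 1.22, immediate-early genes at 1.44, excitatory neuron markers at 1.66 and neural stem cell genes at 2.45. With 1000 bp at both gene ends left out, a choice made after the data were examined, 3 lists lay outside: the olfactory and vomeronasal receptors and the Polycomb list at 0.37, so 2 of the 7 remained. Of the 7, 4 stayed outside with the trend removed, where excitatory neuron markers came to 10.04, imprinted genes to 4.58 and neural stem cell genes to 3.84. With background subtracted 4 stayed, and olfactory receptors came to 50 (their median ratio became 0), excitatory neuron markers to 3.05 and imprinted genes to 2.56. With deposited values as they stand 4 stayed, and immediate-early genes came to 18.73, excitatory neuron markers to 6.95 and inhibitory neuron markers to 4.86. With the mean in place of the median 5 stayed, and excitatory neuron markers came to 10.68 and neural stem cell genes to 2.84. Only vomeronasal receptors stayed outside throughout. On the high side lay presynaptic genes at 98.77 with the trend removed and 98.08 with the mean, sperm genes at 99.6 with the mean and 99.29 with deposited values, and memory and aging genes at 98.37 with deposited values. Newly on the low side were the Polycomb list at 0.57 with the trend removed and 1.94 with the mean, and nuclear genes of mitochondrial respiration at 2.015 with background subtracted and 0.72 with deposited values.

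**Figure D2:**
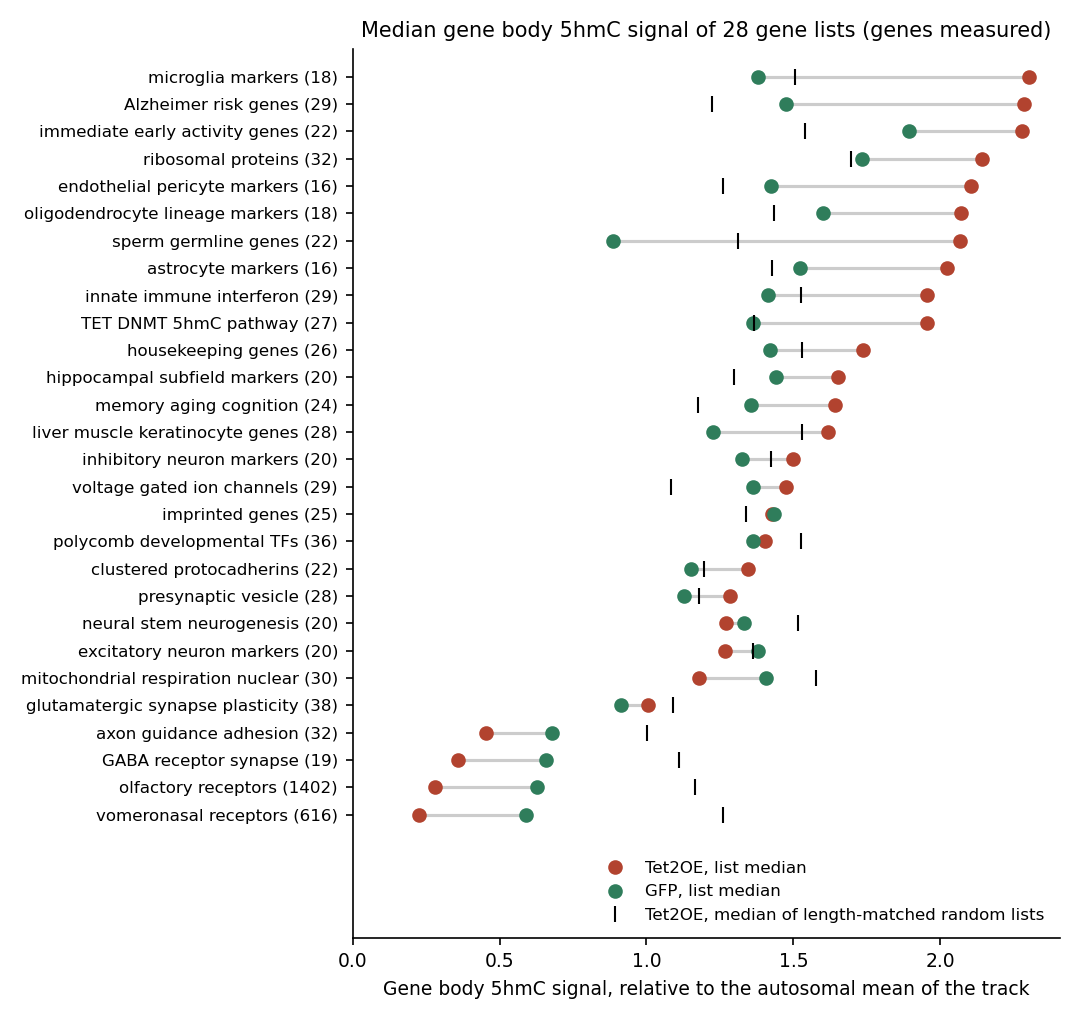
Median gene body 5hmC signal relative to the autosomal mean (horizontal) for 28 gene lists, with the number of genes measured in parentheses, in Tet2OE (red) and GFP (green). Black ticks are the medians of length-matched random lists in Tet2OE; Alzheimer risk genes at 2.28 lie above theirs, and GABA receptor genes at 0.360 lie below.

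Across the genome, 5hmC signal was concentrated in genes, and the contrast was larger in the Tet2OE track. A larger share of fragments captured without 5hmC in GFP could also give this. With 1 track per group, a difference in 5hmC cannot be told apart from it. Protein-coding gene bodies held 1.299 ± 0.020 times the autosomal mean in Tet2OE (block bootstrap SE) and 1.14 ± 0.01 in GFP, a log2 ratio of 0.19, and bins at the boundary of a protein-coding gene held 1.61 ± 0.02 and 1.297 ± 0.011, a ratio of 0.31. Sequence outside annotated genes held 0.764 ± 0.014 and 0.882 ± 0.007, a ratio of -0.21. Genes of long noncoding RNAs had 1.08 ± 0.02 and 1.05 ± 0.01, and pseudogenes and small RNA genes 0.776 ± 0.042 and 0.949 ± 0.022. Over 264884 bins of 10 kb, 45596 were higher in Tet2OE and 110736 lower, where draws gave 52107 and 21443, so the number higher did not exceed that from counting error. Centring of the bins gave 77675 higher and 82138 lower, quantile normalization 55242 and 55254, and removal of the trend 52097 and 47775.

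Regions of strong enrichment were found in Tet2OE. Of 2456282 bins of 1 kb, 170709 (6.95%) in Tet2OE and 0 in GFP had at least 3 times the mean of their track. With thinning to the GFP depth and form, only 7385 such bins remained in Tet2OE. Bins left out as extreme, among them those with the most GFP signal, were not counted. The stretch on chromosome 2 from 98657001 to 98673000, which held 1.66% of the deposited GFP total, was left out in this way. The GFP form holds a floor, and the thinned Tet2OE carried the same floor. Over all draws, however, the thinned Tet2OE held 1.93 times the GFP signal above the floor. The draws therefore cannot show whether the floor gave the count of 0. A count of 0 in this form, taken without the bins left out as extreme, does not show that enriched bins were absent from GFP. Tet2OE pileup exceeded the GFP local background by at least 3 times in 5270 bins, against 16.6 ± 3.5 with draws in place of GFP. Grouped by Tet2OE density, GFP fragments per kb lay within 3.53% of a straight line, 0.863 plus 0.0486 times the Tet2OE fragments per kb, over 15 classes. The lowest class, 145740 bins (5.93%), was left out of the fit; it had 2.04 fragments per kb in Tet2OE and 0.576 in GFP, -40.1% from the line. The constant does not hold there. With this class in the fit, the line missed a class by up to 59.7%. Taken over the bins of the fitted classes, the constant would come to 51.7% of their GFP fragments. With the lowest class in the fit and all bins counted, it would come to 51.0%. From the lowest to the highest fitted class, density differed 18.1-fold in Tet2OE and 4.33-fold in GFP.

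**Figure D3:**
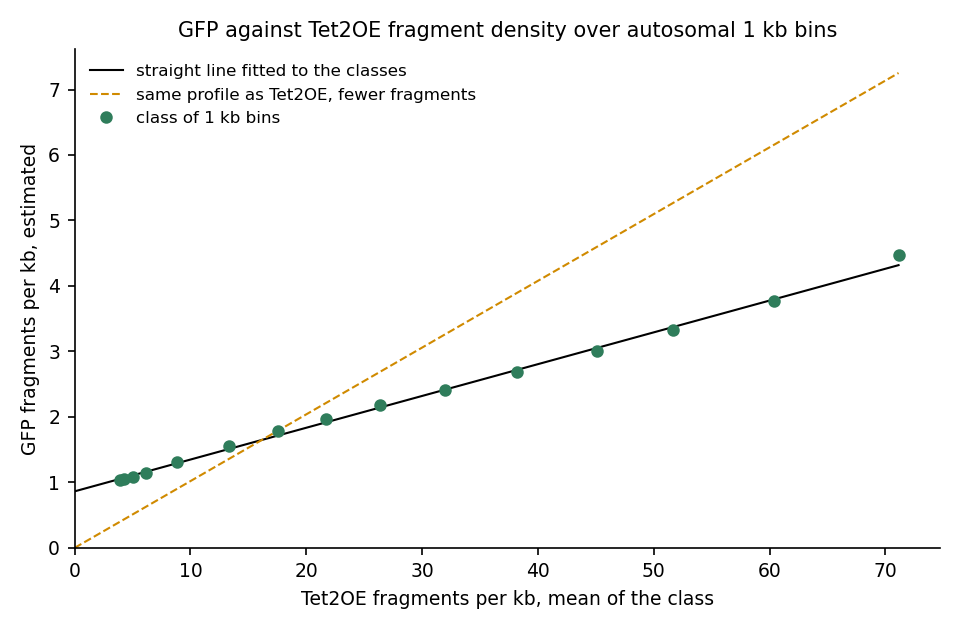
Estimated GFP fragments per kb (vertical) against Tet2OE fragments per kb (horizontal), each green point being a class of autosomal 1 kb bins, without the lowest class, which was not fitted and lies at 0.576. The black line is the straight line with constant 0.863 and slope 0.0486, and the dashed line shows a GFP profile equal to that of Tet2OE with fewer fragments.

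Chromosomes differed in the same direction as genes. The gene-dense chromosome 11 held 1.35 times the autosomal mean in Tet2OE and 1.15 in GFP, and chromosome 3 held 0.746 and 0.887. Chromosome X held 0.246 in Tet2OE and 0.397 in GFP, a log2 ratio of -0.69 ± 0.01, and Y held 0.159 and 0.387, a ratio of -1.28 ± 0.01. The labels do not give the sex of the mice.

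**Figure D4:**
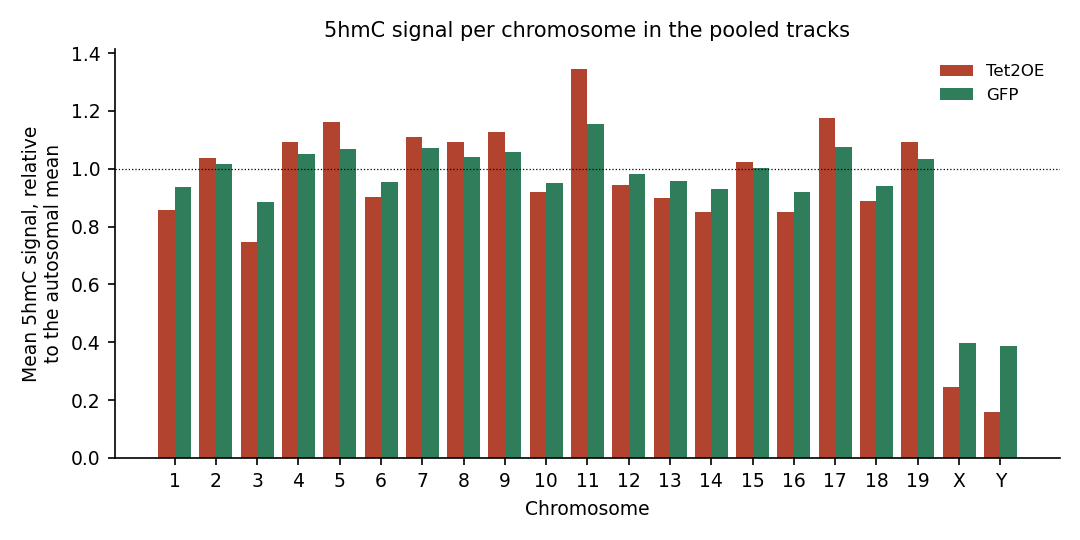
Mean 5hmC signal per chromosome relative to the autosomal mean in Tet2OE (red bars) and GFP (green bars), 1 pooled track each. Autosomes range from 0.746 to 1.35 in Tet2OE and from 0.887 to 1.15 in GFP, and X and Y lie below all autosomes in both.

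The Tet2 gene itself, on chromosome 3 from 133463677 to 133545136, was examined because viral Tet2 coding sequence would add fragments over its coding exons. The Tet2OE pileup over 163 windows of 500 bp had a median of 3.45 fragments per bp, against 4.71 in flanks of 20 kb. The highest window, from 133487501 to 133488000, reached 25.5 fragments per bp, and the highest in the flanks reached 18.7. At least 0.5 of the highest value was reached in 21 windows of the gene. Gene body signal was 1.02 times the autosomal mean in Tet2OE and 1.04 in GFP. Exons were not mapped here, so this neither shows nor excludes viral sequence in the Tet2OE track.

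**Figure D5:**
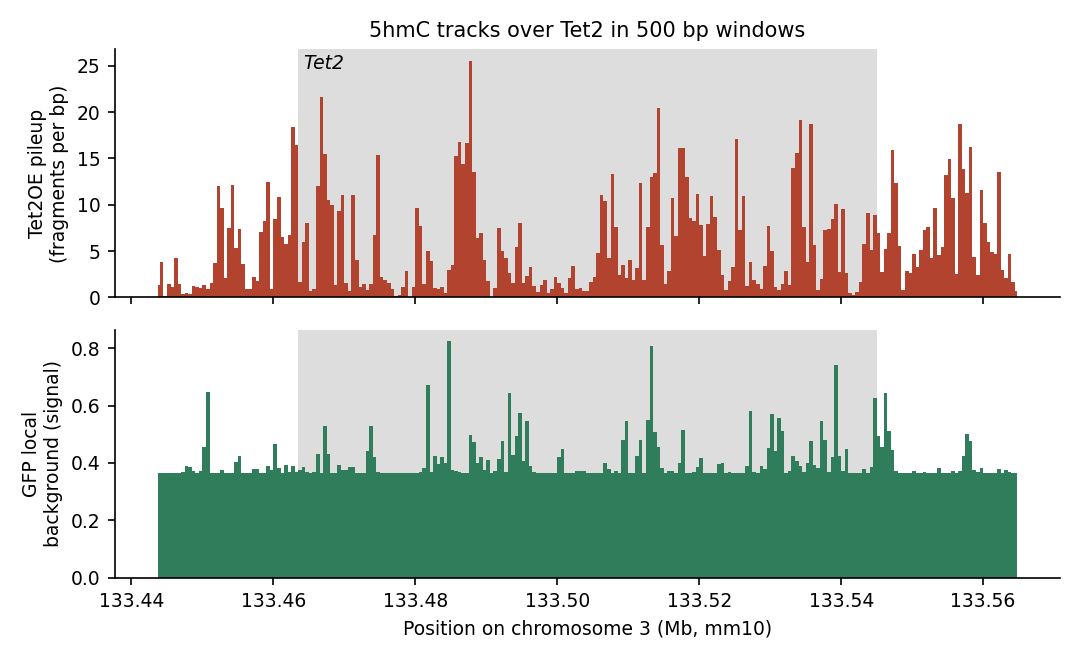
Tet2OE pileup in fragments per bp (top, red) and GFP local background in the deposited signal unit (bottom, green) in 500 bp windows along chromosome 3 (Mb, mm10), with Tet2 shaded. The highest Tet2OE window reaches 25.5 fragments per bp, and the GFP track rests on its floor of 0.365 over most of the region.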

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

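All tests in this part were chosen after the results had been seen. Of 44 sequences that entered no comparison, being outside the assembled chromosomes, 2 unplaced sequences of chromosome 4 had a mean deposited signal in Tet2OE above that in GFP. The sequence of 206551 bp had 0.3998 in Tet2OE and 0.3968 in GFP, and that of 1630 bp had 1.05 and 0.555. The difference was not tested, and no GFP value can lie below the floor of 0.365.

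The profile of GFP over genes was flatter than that of Tet2OE, with a slope of the log2 ratio on log2 signal of 0.43. The steepest slope over 20 thinned draws in the same form was 0.00826 in size, so random loss of Tet2OE fragments does not produce this. The draws and the reading of GFP both rest on Tet2OE fragments, so a flat result was built in. The draws cannot show what the form does to GFP fragments spread otherwise within genes. They also held 1.93 times the GFP signal above the floor. Depth and form are therefore not excluded. A larger share of fragments captured without 5hmC in the GFP pool is a candidate explanation: mitochondrial DNA, taken here to carry little 5hmC, was 4.36 times as abundant per autosomal fragment in GFP as in Tet2OE (draws up to 1.61), although carry-over of mitochondria in the sort might also raise it. A gain of 5hmC with Tet2 at sequence already rich in it stays open and cannot be told apart, because there was only 1 track per group. The same holds for a difference between library batches, which the labels do not give, and neither was tested.

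Genes above the trend of ratio on signal lay mostly on X. With the trend removed, 58 eligible genes lay above it by at least 0.5, and 46 of them were on X, where their share of eligible genes would give 0.726. This is a position against the trend and not a higher ratio: chromosome X had a log2 ratio of -0.69. The X genes furthest above the trend, Reps2, Phex and Arhgap6, had ratios of -0.13, -0.28 and -0.47. Before the trend was removed, 1334 of the 1335 eligible genes called higher were autosomal. Counting error in the thinned draws gave fewer genes off the trend: 58 lay above and 59 below, against 3 and 0 on average over 3 draws. The residual SD over all eligible genes was 1.99 times that of draws, or 1.74 times by median absolute deviation. For autosomal genes alone the residual SD was 1.84 times that of draws. The draws held 1.93 times the GFP signal above the floor, and their trend was fitted on Tet2OE signal alone, so they may understate counting error in GFP. The lower copy number of X in male cells is a candidate explanation, since it may lower unenriched background there. The count of 46 prompted this explanation and cannot test it, because any other cause acting on X would give the same count. The labels do not state the sex of the mice, and no biological explanation was tested.

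Genes below the trend tended to lie close together. Of 59 such genes, 22 had another within 2 Mb, where 10000 random sets of 59 eligible genes gave 6.92 on average and 21 at most, and 13 were on chromosome 4. Sequence present in more copies per cell than the assembly holds may raise unenriched background at such loci, and the count of 22 leaves this open, because copies per cell were not measured. A difference in 5hmC between the groups at these genes cannot be told apart from it.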

How the results depend on the processing

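Alternatives were listed before the data were examined, except for extreme bins kept, both gene ends trimmed, autosomes only and deposited values as they stand, which were chosen after seeing the data. The cause of a change was not tested unless stated. Of the counts and values that answer a comparison, 52 stayed within 1.5 times or within their error under an alternative and 49 moved. Of the values of single genes and lists, 345 stayed, 490 moved by more than their counting error, 16 put a list back inside the central 95% and 11 changed the sign of a gene called higher or lower. Of named genes within the threshold, 46 values changed sign.

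In the pairs that follow, the number higher in Tet2OE stands before the number lower. Median centring gave 11380 genes higher, 89 eligible genes higher and 1018 lower, 77675 bins higher, and Tet2 at -0.31, since it subtracts 1 number from every ratio. Quantile normalization gave 9943 genes higher, 32 and 80 eligible genes, and 55254 bins lower. Removal of the trend gave 10688 genes higher, 58 and 59 eligible genes, and 47775 bins lower. Background subtraction gave 2503 and 1096 eligible genes, 74843 bins higher and 0.40 for protein-coding bodies. A pseudocount of 0.5 gave 6882 genes lower and 810 and 209 eligible genes. Without the lower quartile of signal, 5078 genes, 28 eligible genes and 67277 bins were lower. A threshold of 1 left 8674 and 4867 genes, 2 and 86 eligible genes, and 9220 and 60184 bins. Fewer genes entered with both ends trimmed (9468 and 6090), with at least 5000 bp (7368 and 5184) and with protein-coding genes only (7099 and 4177). Trimmed ends left 3 lists outside the central 95%, of which 2 were outside before. Deposited values as they stand gave 2425 eligible genes higher. Bins of 5 kb gave 115812 and 217181, and bins of 50 kb 6472 and 21654. Enriched 1 kb bins numbered 11733 in GFP and 431468 in Tet2OE at 2 times the mean, 4976 in Tet2OE at 5 times, 21829 with 5 kb bins and 7385 after thinning. Bins left out as extreme did not enter the counts of 1 kb bins. GFP and full Tet2OE differ in depth and form. A draw of Tet2OE thinned to the GFP depth and form gave 90161 at 2 times the mean, 6 at 5 times and 124 with 5 kb bins. For X the median of bins gave -0.61 and extreme bins kept gave -0.61, and extreme bins kept gave 0.25 for protein-coding bodies.

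Of called genes, sign changed under quantile normalization for the Ppfia2 gene body at 0.042, the Pax7 gene body at -0.0292 and the Dnmt1 gene body at -0.0683. It changed with the trend removed for Scube3 at -0.0304, Erbb4 at 0.0506, Ptprc at 0.0116, Ppfia2 at 0.0431, Pax7 at -0.0319, Vmn2r1 at 0.0011 and Dnmt1 at -0.0693, and with deposited values as they stand for C130026I21Rik at 0.18.

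No paired analysis was possible because the groups share no replicate number and each is 1 pooled track. Leaving out replicates, promoter windows, GC content, repeats, the first 1000 bp of genes, the exon to intron ratio of Tet2, and exon, intron and CpG island classes were not run. The depth of the GFP track limits the comparison: genes below the limit of 100 fragments gave many calls by counting error alone.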

Other observations

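The genes described in this part were picked out after their values were seen, and all tests were chosen then. A cluster of zinc finger genes on chromosome 4, between 145412232 and 147812229, held 10 of the genes below the trend. Their signal ran from 0.510 to 1.29 times the autosomal mean in Tet2OE and from 1.10 to 2.43 in GFP, with log2 ratios from -1.70 to -0.71. Among them were Zfp982 at -1.11 ± 0.11, Zfp978 at -0.87 ± 0.06 and Zfp984 at -1.19 ± 0.15. On chromosome 8, 4930467E23Rik at -1.05 ± 0.10 lay near Gm21119. Stretches that held bins left out as extreme overlapped Zfp600, Zfp978, 4930467E23Rik and Gm21119.

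On autosomes, 12 genes were above the trend of ratio on signal by at least 0.5. Sgms2, a sphingomyelin synthase gene on chromosome 3, had a ratio of 0.50 ± 0.07, or 0.74 above the trend. Traf5, an adaptor of tumour necrosis factor receptors, had 0.45 ± 0.11, or 0.65 above the trend. Fam163a had 0.56 ± 0.09, Slc25a12, the mitochondrial aspartate and glutamate carrier of neurons, 0.70 ± 0.07, and Tacc1, a centrosomal protein gene, 0.86 ± 0.06. In each of these 5 genes both parts of the gene, split at the midpoint, had a positive ratio. In Cdc42bpa, Bicd1, Ubr1, Alms1, Cdh20 and Intu the parts differed in sign, and in Gm4724, at -0.66 ± 0.11, both were negative. On average over 3 thinned draws, 3 genes lay above the trend.

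The 10 positions with the most GFP signal held 3.22% of the deposited GFP total, which includes the floor. Shares of the deposited tracks cannot be set against each other, because 72.0% of GFP positions rest on that floor, so those of GFP alone are given. On chromosome 2, the region from 98657001 to 98673000 held 1.66%. On chromosome 14, the region from 19410001 to 19425000 held 0.522%, and on chromosome 9, the regions from 2995001 to 3043000 and from 35300001 to 35311000 held 0.447% and 0.295%. On chromosome 6, the region from 103644001 to 103655000 inside Chl1, a neural adhesion gene, held 0.0502%. The mitochondrial genome held 354 Tet2OE fragments and an estimated 158 GFP fragments.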
